A study of Homo sapiens with 91 samples.

How the data were processed

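Total RNA of synchronised U2OS cells, extracted with Qiagen RNeasy columns and labelled with the Agilent Quick Amp method, was hybridised on Agilent arrays by the authors: Cy5 for the time point and Cy3 for a common reference of asynchronous U2OS cells. Per the labels, thymidine was used at 2.5 mM; the double block took 18 h, a release of 8 h and 18 h more, and the thymidine-nocodazole course took 17 h of thymidine and then 100 nM nocodazole, with floating cells added back during the first 6 h. The values are the deposited log2 ratios of sample over reference as the authors processed them; normalization and software are not given in the sources used here, and neither is the base of the logarithm. Base 10 was ruled out by the range of the values, −9.38 to 10.4, which exceeds that of a scanner; natural logs were not. No value was missing, and 93861 values were exact zeros. The table held 45220 probes: 31332 with 1 gene, 93 with several genes and 13795 with no gene named here. Names came from the gene identifiers of the array and a table of the GRCh38.p14 annotation, in which 41 probes' identifiers were not found. Positions are not given, since the build behind the array is not named.

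Probes with 1 gene were averaged to 18334 genes, 7759 of them with more than 1 probe. A gene had to be measured on at least 80% of the arrays of a fit, which removed none. The log ratios were used without further normalization; array medians lay between −0.001 and 0.036. No pair of arrays was identical. Courses were the replicates, since the labels give each double thymidine course its own start. Time points of a course come from the same cells' synchronisation. The p values of the periodic fits, however, rest on the scatter of single arrays. They do not measure the spread of a wave between courses, which the SDs over courses give. Signal over background was not in the table, so the depth behind a single log ratio is unknown and the number of arrays limits the precision.

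The period was the one, on a grid from 14 to 34 h in steps of 0.25 h, that left the least residual variance in the G1/S and the FOXM1 and G2/M lists together (47 genes). Each gene was then fitted in limma 3.58.1 (R 4.3.3) with an intercept and a linear trend per course and a cosine and a sine of that period, and the moderated F test on both terms was adjusted over all genes by Benjamini-Hochberg. A gene was called periodic at an adjusted p under 0.01 and a fitted peak-to-trough of at least 1.5-fold. The difference between synchronisations used the interaction of both terms at the same limits. The 8 h against 0 h comparison used limma's moderated t statistic in a fit of all time points up to 38 h with the course as a block, an adjusted p under 0.05 and at least 1.5-fold. Folds and peak times come from the joint fit of the 3 courses, and their errors are SDs over courses fitted one by one, whose mean can differ from the joint value. The second-cycle measure is the slope of a gene's detrended values on its fitted wave after the first period, divided by that slope within the first period, as the median over genes of a course.

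A set of 28 gene lists was fixed from textbook knowledge, with 527 members, of which 499 were measured. There were 14 lists of cell cycle processes and factors, lists of stress and signalling responses, ribosomal and housekeeping genes, and haematopoietic and epithelial markers. Log ratios to a U2OS reference do not show whether a marker was absent or whether other cells were present. Lists were tested for more periodic calls with one-sided Fisher exact tests and for a shift at 8 h with limma's camera at a preset correlation of 0.01, and with the correlation estimated per list; p values were adjusted over the lists. A list's calls were also counted with p adjusted over the list alone. Named genes followed a rule: all members of the E2F, RB, MuvB and FOXM1 list; from each list the 3 called members with the widest waves and up to 2 uncalled ones with the largest adjusted p; the 10 widest waves of a synchronisation; the 10 largest rises and 10 largest falls at 8 h with the same sign in all courses; and up to 10 genes that differ between synchronisations. The lists, comparisons, thresholds, the naming rule and the alternatives not marked as added were fixed before the data were examined.

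The alternatives were centring or quantile normalization of arrays, other limits on missing values, the most variable probe of a gene, no minimum fold or 2-fold, no trend, a period 2 h shorter or longer, prewhitened values, leaving out 0 h arrays, arrays marked as second, times after 38 h, the first 6 h of the nocodazole course or each course in turn, no course block, other windows for the early comparison, and periods from the G1/S or the FOXM1 and G2/M list alone. Added after seeing the data were exact zeros as missing values, terms for interleaved sets of arrays, leaving out one of these sets, a covariate of housekeeping and ribosomal genes, other periods for the thymidine-nocodazole course, and the offset between synchronisations.

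The steps were tested on simulated data, in which the arrays of a course were put in random order and waves or shifts of known size were added to 200 genes. The double thymidine fit called 41.8%, 95.5% and 100% of waves of 1.5, 2 and 3-fold, the thymidine-nocodazole fit 1.49%, 22.4% and 56.1%, the difference 14.9%, 40.3% and 72.7% and the 8 h against 0 h fit 13.4%, 46.3% and 83.3%. Unchanged genes called were 0, 0, 8 and 14. The added waves had exactly the period of the fit and kept their size, so recovery can be lower for waves that shrink or differ in period. A simulated period of 20 h was found at 19.75 h. Figures were drawn with matplotlib 3.10.9. Probes without a gene named here and probes with several genes entered no comparison.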

Results

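Gene expression was measured through the cell cycle of U2OS, a human osteosarcoma cell line, on 91 dual-colour Agilent arrays. Each array compared total RNA of one time point, in the Cy5 channel, with a common RNA of asynchronously growing U2OS cells, in the Cy3 channel, so a log ratio above 0 means a higher level than in growing cells. Cells were synchronised in different ways. A double thymidine block, which stalls DNA synthesis and holds cells at the G1/S border, was followed in 3 courses of 24, 20 and 24 arrays, up to 46, 38 and 46 h after release. A thymidine block followed by nocodazole, which takes microtubules apart and holds cells in mitosis, was followed in 1 course of 23 arrays up to 44 h, so its values have no replicates. Arrays were 2 h apart, and 8 arrays of course 1 were marked as a second array in their labels. The log ratios of an array had a standard deviation (SD) of 0.433 to 0.926, with a median over arrays of 0.73 in the thymidine-nocodazole course and of 0.56, 0.59 and 0.54 in double thymidine courses 1, 2 and 3. The number of courses limits the precision of every value. The deposited log ratios were read as log2; the base is not given in the sources used here, and folds would be larger if the values were natural logs.

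The first question was which genes rise and fall with the cell cycle after release from the double thymidine block. In the 3 courses, 187 of 18334 genes were called periodic, and most peaked at either of 2 times. The fit did not require a second wave, so a gene that changed once after release could also be called. Of the 187 genes, 69 peaked in the first 3.04 h of an 18.25 h cycle and 69 between 9.13 and 12.2 h, while 5 peaked between 6.08 and 9.13 h. The widest wave was that of SHISA3, a gene of a family that restrains WNT and FGF receptors, which peaked at 11.7 h with a fitted peak 3.45-fold above its trough in the joint fit; courses fitted one by one gave a mean log2 peak-to-trough of 1.87 ± 0.31 (SD, n = 3). Next to it in the late group stood the inducible HSP70 gene HSPA1A at 2.73-fold and 11.4 h, FAM83D, which encodes a spindle protein, at 2.58-fold and 9.68 h, and KIF20A, a kinesin of cytokinesis, at 2.36-fold and 12.0 h. The early group was led by the linker histone gene H1-1 at 2.68-fold and 2.83 h, the transcription factor gene MYB at 2.66-fold and 1.40 h, and FAM111B at 2.63-fold and 1.27 h. The histone H4 genes H4C3, H4C13 and H4C2 had folds of 2.59, 2.44 and 2.38 and peaked somewhat later, at 3.62, 3.49 and 3.61 h. FAM111B was not called without course 1.

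Of the 187 genes, 56 belonged to at least 1 of the lists fixed beforehand. Genes of G2 and mitosis peaked late. Of 30 measured FOXM1 and G2/M targets, 22 were periodic, with a mean peak at 11.1 h (course SD 1.36 h, n = 3) and folds from 1.53 to 2.36. In the joint fit the folds were 2.36 for KIF20A, 2.09 and 2.07 for the mitotic kinase genes PLK1 and AURKA, and 2.02 for the cyclin B1 gene CCNB1. Courses fitted one by one gave mean log2 peak-to-trough values of 1.33 ± 0.09, 1.12 ± 0.10, 1.16 ± 0.33 and 1.08 ± 0.24 for these genes in turn (SD, n = 3). AURKB and TACC3 of the same list were not called, with fitted folds of 1.29 and 1.27. Of 34 kinetochore and spindle checkpoint genes, 6 were periodic, with a mean peak at 10.6 h (course SD 1.77 h, n = 3), among them CENPE at 2.00-fold, CENPA at 1.86-fold and BUB1 at 1.71-fold. Among 12 mitotic kinesins, 4 were periodic: KIF20A, KIF23 at 1.79-fold, KIF18A at 1.70-fold and KIF2C, chosen after its values were seen, at 1.54-fold. The centriole and centrosome list had 2 periodic genes of 15, NEK2 at 1.87-fold and CEP55 at 1.58-fold. In the condensin and cohesin list the only call of 19 was SGO2, a protector of centromeric cohesion, at 1.99-fold, and in the anaphase-promoting complex list the only call of 16 was its activator CDC20, at 1.74-fold. CDC20 was no longer called without course 1, without course 2 or without course 3.

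Genes of S-phase entry peaked early. Of 17 G1/S regulators, 6 were periodic, with a mean peak at 1.26 h (course SD 0.72 h, n = 3). The cyclin E genes CCNE2 and CCNE1 had folds of 2.26 and 1.60 and peaked at 1.08 and 0.20 h, and the licensing factor gene CDC6 had a fold of 1.59 and peaked at 1.95 h. GMNN and RBL1 were not called, at 1.06-fold and 1.09-fold. Of 41 replication licensing and fork genes, 7 were periodic, with a mean peak at 2.34 h (course SD 0.56 h, n = 3), including RFC4 at 1.67-fold, MCM2 at 1.65-fold and CLSPN at 1.59-fold. Of 45 replication-dependent histone genes, 5 were periodic, with folds from 2.22 to 2.68 and a mean peak at 3.39 h (course SD 1.76 h, n = 3). Their members are close in sequence, and without course 3 the mean peak of the histone genes then called lay at 16.9 h. H1-1, H4C13 and H4C2 were not called without course 1, without course 2 or without course 3, and H4C3 not without course 1 or without course 3. The chromatin assembly gene CHAF1B was the only call of 15 in its list, at 1.51-fold, and not called without course 2, and RMI2, which acts in double Holliday junction dissolution, the only call of 20 in the Fanconi and recombination list, at 2.09-fold. The step from the mean peak of the G1/S list to that of the FOXM1 and G2/M list was 9.82 h (course mean 9.85 ± 0.65 h, SD, n = 3). The list of cyclins, CDKs and inhibitors held members of both groups: 6 of 29 were periodic, among them CCNE2, CCNB1 and CDC25C, the last at 1.62-fold with a peak at 10.5 h; CDC25C was not called without course 2, and CLSPN not without course 3.

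The series also asks about the E2F and FOXM1 factors that regulate these genes. Of 21 genes of E2F, RB, MuvB and FOXM1 factors, 1 was periodic in its own transcript. E2F2 peaked at 0.88 h with a fold of 1.52 and an adjusted p of 3.7e-05. Of the array spots for E2F2, at least 1 had an unadjusted limma p of 0.05 or more when fitted by itself. E2F1 had an adjusted p of 2.4e-05 and a fold of 1.35, below the minimum fold of 1.5, with a fitted peak at 3.54 h. E2F8 had an adjusted p of 2.3e-04 and a fold of 1.46, with a fitted peak at 1.78 h. The FOXM1 transcript had a fitted fold of 1.04 and an adjusted p of 0.95. For MYBL2, the MuvB partner B-MYB, the fitted fold was 1.24 with an adjusted p of 0.38, and for E2F7 it was 1.28 with an adjusted p of 0.58.

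Outside the cell cycle lists, heat shock genes had the largest share of periodic members: 4 of 10, with a mean peak at 11.6 h (course SD 1.43 h, n = 3). The call rests on the first cycle, since the slope of their values on the fitted wave in the second was 0.06 ± 0.09 of that in the first (SD, n = 3 courses). They were HSPA1A, HSPA8 at 1.73-fold, HSPH1 at 1.60-fold and BAG3, chosen after its values were seen, at 1.54-fold. Each of HSPA1A, HSPA8 and HSPH1 was no longer called when any of the 3 courses was left out. Single calls came from the immediate early list (ATF3, 1 of 18, at 1.60-fold), the ATF4 and unfolded protein list (VLDLR, 1 of 16, at 1.75-fold) and the interferon list (IFIT1, 1 of 17, at 1.72-fold). VLDLR and IFIT1 were not called without course 1, without course 2 or without course 3, and ATF3 not without course 1 or without course 2. Of the array spots for ATF3, at least 1 had an unadjusted limma p of 0.05 or more when fitted by itself. None of 16 nucleotide synthesis genes, 20 p53 targets, 14 cholesterol synthesis genes, 13 NF-kB and inflammatory genes, 14 hypoxia and glycolysis genes, 15 circadian clock genes, 16 extracellular matrix genes, 19 ribosomal protein genes and 10 housekeeping genes was called by limma. The 6 haematopoietic and 7 epithelial markers were not called either. Adjusted over the list alone, the counts were the same except for 2 Fanconi and recombination genes, 2 immediate early genes and 1 clock gene.

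By a one-sided Fisher exact test, 9 of the 28 lists held more periodic genes than the other genes did. The adjusted p was 6.6e-37 for FOXM1 and G2/M targets, 1.6e-07 for G1/S regulators, 1.6e-06 for licensing and fork genes, 2.8e-06 for cyclins and CDKs, 6.2e-06 for kinetochore genes, 9.8e-06 for heat shock genes, 1.9e-05 for kinesins, 3.2e-04 for histones and 0.031 for centrosome genes. The G1/S and the FOXM1 and G2/M lists also set the period, so their counts are not independent of it. The cyclin, kinetochore, kinesin and centrosome lists share called genes with these lists, such as CCNE2, CENPE, KIF20A and NEK2. The counts of those lists are thus not independent of the period either. Peak times recurred between courses: genes called without course 1, 2 or 3 peaked within 4.56 h, 0.25 of a period, in the left-out course in 98.96%, 100% and 96.6% of cases, against 50% by chance. The number of calls depended on single courses, with 96 genes without course 1, 68 without course 2 and 175 without course 3. Enriched lists numbered 8, 7 and 11 in turn. With a period shorter by 2 h, 120 genes were called.

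**Figure D1:**
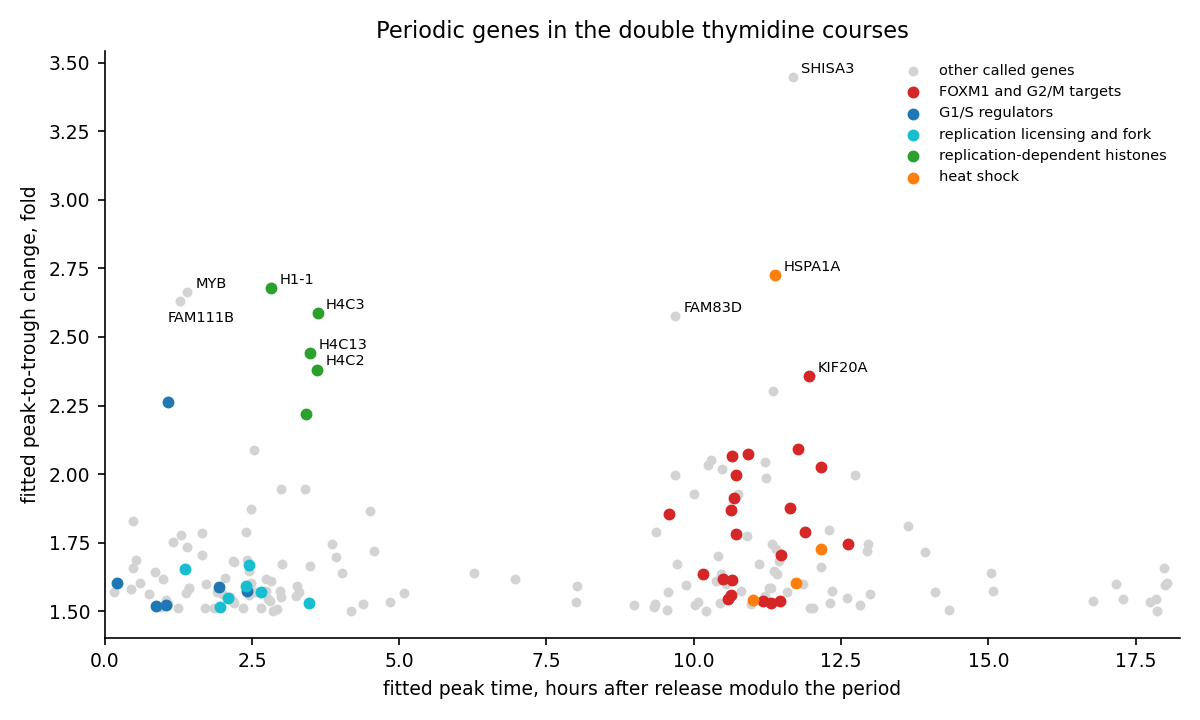
The 187 periodic genes after double thymidine release, with fitted peak time in hours on the horizontal axis and fitted peak-to-trough fold on the vertical axis; each point is a gene, coloured points belong to the gene lists in the legend and grey points to none of these. Genes gather within the first 3.04 h and between 9.13 and 12.2 h, and SHISA3 stands highest at 3.45-fold.

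Taken as a median over the called genes, the slope of the values on the fitted wave was smaller in the second cycle than in the first. The period that left the least variance in 47 marker genes was 18.25 h and covered 35.2% of their variance; the courses alone gave 17.5, 16.5 and 19 h. The mean log ratio of the FOXM1 and G2/M targets was −0.65 ± 0.05 at 0 h, 0.48 ± 0.06 at 12 h, −0.33 ± 0.16 at 18 h and 0.31 ± 0.26 at 26 h (SD over courses, n = 3). The mean of the G1/S regulators was 0.24 ± 0.15 at 0 h, −0.34 ± 0.06 at 10 h, 0.41 ± 0.07 at 20 h, −0.04 ± 0.13 at 28 h and 0.13 ± 0.13 at 36 h. Over all 187 genes, this slope in the second cycle was 0.32 ± 0.06 of that in the first (SD, n = 3 courses). The ratio was 0.36 ± 0.05 for the periodic FOXM1 and G2/M targets, 0.40 ± 0.17 for the periodic G1/S regulators and 0.06 ± 0.09 for the 4 periodic heat shock genes. Phase and the 18.25 h period were held fixed, so a course with another period can have a lower ratio without a smaller swing.

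**Figure D2:**
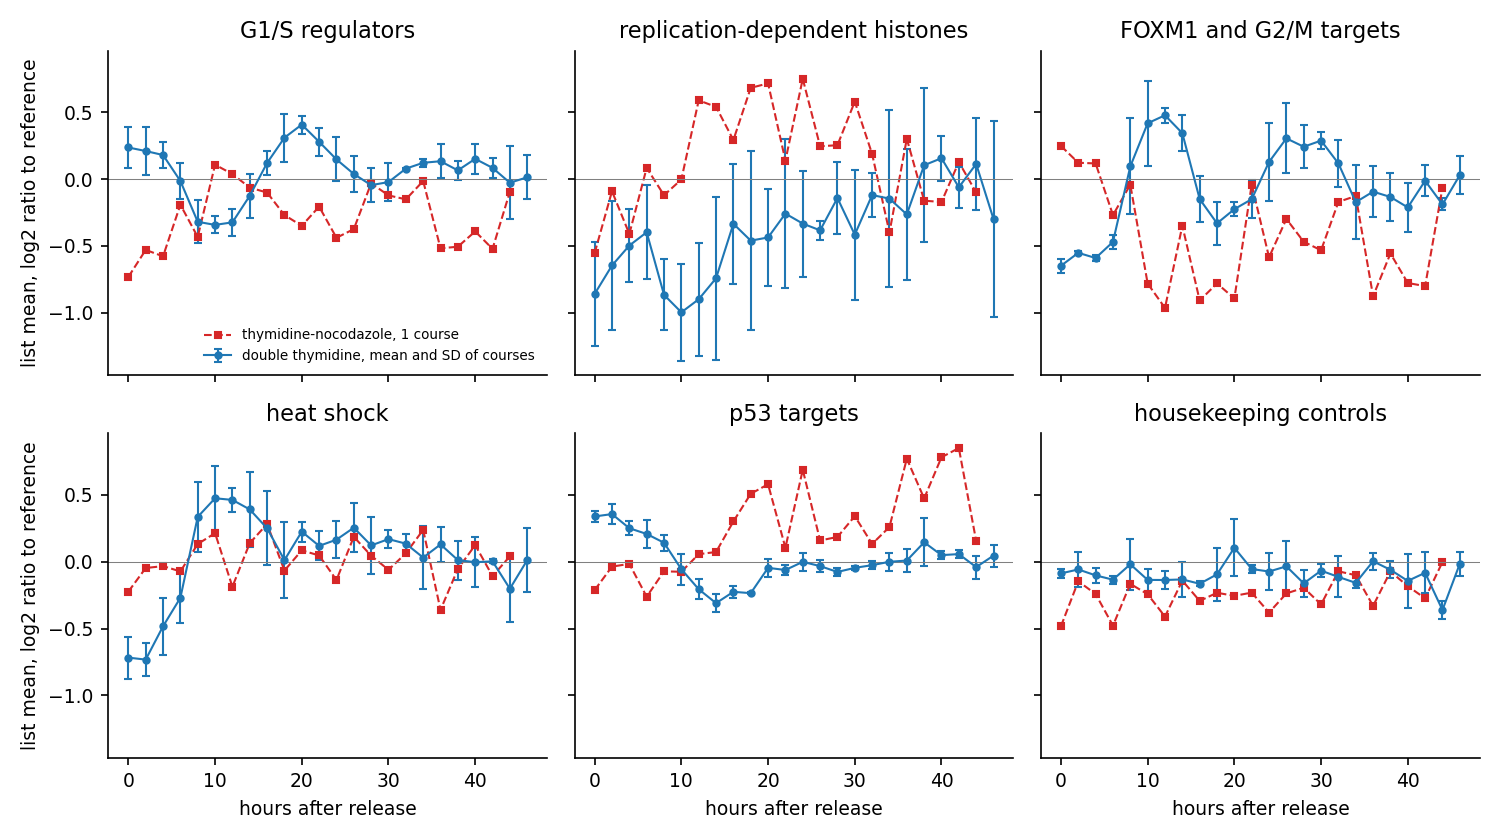
Mean log2 ratio of the members of chosen gene lists against time after release in hours, with the mean of the double thymidine courses and bars of 1 SD between courses (3 courses to 38 h, 2 after that) and the single thymidine-nocodazole course. The FOXM1 and G2/M targets stand at −0.65 at 0 h of double thymidine and at 0.25 at 0 h of thymidine-nocodazole.

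The next comparison asked what separates cells 8 h after double thymidine release from cells still at the block, at 0 h. At 8 h, 345 genes were higher and 475 were lower, and 337 and 465 of them moved that way in all 3 courses. The largest rise was that of ESM1, which encodes a secreted proteoglycan, with a log2 change of 3.05 ± 0.38 (SD over courses, n = 3; 8.28-fold, adjusted p 1.3e-07), followed by HSPA1A at 3.01 ± 1.11 and FAM83D at 2.21 ± 0.91. The ephrin receptor gene EPHA4 rose by 2.03 ± 0.37, the keratin-associated protein gene KRTAP2-3 by 2.01 ± 0.63, the hair keratin gene KRT33A by 1.98 ± 0.69, and the EGF receptor ligand gene TGFA by 1.95 ± 0.79. The largest fall was that of the fucosyltransferase gene FUT1, with a change of −2.96 ± 0.78 (adjusted p 1.7e-07), followed by the hormone gene FGF21 at −2.47 ± 1.49, the antisense RNA DNAJC9-AS1 at −2.02 ± 0.93 and MYB at −1.98 ± 0.64.

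Further falls were those of LOC105372255 at −1.88 ± 0.39, FAM111B at −1.80 ± 1.47, SYBU at −1.79 ± 0.41, LRIG3 at −1.75 ± 0.93, DLGAP1-AS6 at −1.71 ± 0.80 and GAS1, a gene named for growth arrest, at −1.71 ± 0.50 (SD over courses, n = 3). In MOK, ARHGAP9 and CDH3, which ranked among the 10 largest rises, a single course carried the mean: MOK changed by 5.70 in course 2 and by 0.27 and 0.56 in courses 1 and 3, and ARHGAP9 and CDH3 changed by 5.01 and 4.87 in course 3 and by at most 0.88 and 0.60 in the others. Of the 820 genes, 104 were also periodic, 46 of them higher and 58 lower at 8 h.

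Among the gene lists, FOXM1 and G2/M targets, heat shock genes and inflammatory genes stood higher at 8 h. Of 30 FOXM1 and G2/M targets, 12 rose and none fell (18 rose when adjusted over the list alone), with a median log2 change of 0.69 and an adjusted p of 7.4e-20 by limma's camera test, or 0.014 with an estimated correlation. Examples were AURKA at 1.41 ± 0.64, KIF20A at 1.32 ± 0.80, PLK1 at 1.16 ± 0.48 and CCNB1 at 1.11 ± 0.29. Of 10 heat shock genes, 6 rose and none fell, with a median of 0.93 and an adjusted p of 9.6e-12, or 4.0e-04 with an estimated correlation. HSPA8 changed by 1.48 ± 0.39 and HSPH1 by 0.81 ± 0.28. Of 13 NF-kB and inflammatory genes, 2 rose, the chemokine genes CCL2 at 1.77 ± 0.86 and CCL20 at 1.67 ± 0.27, with a list median of 0.50 and an adjusted p of 5.7e-04, or 0.014 with an estimated correlation. The epithelial list shifted higher with 1 riser of 7, the keratin gene KRT18 at 0.83 ± 0.32; its adjusted p was 0.027, or 0.040 with an estimated correlation, and its call ended without course 2 or without course 3. Haematopoietic markers had no call in 6 genes (adjusted p 0.71).

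For 4 lists the higher shift was called with the preset correlation only. Mitotic kinesins had 1 riser of 12, KIF20A (4 when adjusted over the list alone), and a median of 0.59, with an adjusted p of 6.5e-05 and an adjusted p of 0.11 with an estimated correlation. Of 18 immediate early genes, 4 rose, FOSL1, IER2, KLF6 and CCN2, by 0.70 to 1.25, and 1 fell, ATF3, at −0.89 ± 0.18; the adjusted p was 0.0052, and 0.12 with an estimated correlation. Of 14 cholesterol synthesis genes, HMGCS1 and NSDHL rose, by 1.20 ± 0.35 and 0.83 ± 0.63 (adjusted p 0.043, and 0.24 with an estimated correlation). Of 16 extracellular matrix genes, THBS1 and TGFBI rose, by 1.25 ± 0.57 and 1.15 ± 0.09 (adjusted p 0.037, and 0.16 with an estimated correlation).

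Lower at 8 h were genes of S-phase entry and of the ATF4 and unfolded protein response. Of 17 G1/S regulators, 7 fell and none rose (8 fell when adjusted over the list alone), with a median of −0.57 and an adjusted p of 9.6e-12, or 1.8e-04 with an estimated correlation. CCNE2 changed by −1.57 ± 0.50, E2F2 by −1.23 ± 0.27 and CCNE1 by −1.22 ± 0.29. Of 41 licensing and fork genes, 8 fell, RFC4 among them at −1.23 ± 0.42, with a median of −0.27 and an adjusted p of 1.2e-08, or 0.014 with an estimated correlation. Of 20 Fanconi and recombination genes, RMI2, RMI1 and FANCL fell (RMI2 at −1.67 ± 0.64), with a list median of −0.27 and an adjusted p of 1.5e-05, or 0.0012 with an estimated correlation. Of 16 genes of the ATF4 and unfolded protein list, 8 fell, with a median of −0.48 and an adjusted p of 3.0e-06, or 0.0017 with an estimated correlation. They include CHAC1, which degrades glutathione, at −1.63 ± 0.48, ATF4 itself at −1.19 ± 0.58, DDIT3 at −1.16 ± 0.23 and VLDLR at −0.96 ± 0.36.

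The other 16 lists did not pass the test. Kinetochore genes went both ways, with CENPA and CENPL higher and KNTC1, DSN1, CENPP and CENPU lower of 34 (adjusted p 0.55). Of 29 cyclins, CDKs and inhibitors, CCNB1, CCNA2 and CDK1 rose and CCNE1 and CCNE2 fell (0.14). The p53 targets had 3 genes lower of 20, TP53INP1, SESN2 and DDB2 (0.053), and the anaphase-promoting complex list 2 higher of 16, CDC20 and UBE2S (0.072). Among E2F, RB, MuvB and FOXM1 factors, E2F2 and E2F8 fell, and FOXM1 had a change of 0.24 ± 0.66. Single or few calls came from nucleotide synthesis (CTPS1 higher), histones (H3C11 higher; the list was called higher without course 1 and lower without course 3), chromatin assembly (CHAF1B lower), condensin and cohesin (ESCO2 lower), interferon response (IFIH1 lower), hypoxia and glycolysis (ENO2 and EGLN3 lower) and the circadian clock (BMAL1 higher, NR1D2 and BHLHE41 lower), and none from centrosome, ribosomal protein or housekeeping genes. The median, the mean and the test differed in sign for histones, nucleotide synthesis, centrosome and haematopoietic lists, all of which were uncalled. Members named here outside the rule for named genes were chosen after their values were seen.

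The 8 h against 0 h fit drew its spread from all 60 double thymidine arrays up to 38 h and held the course as a block. Without the block it called 336 genes in place of 820, without the arrays marked as a second array, to which the 8 h array of course 1 belongs, 526, and from the 0 h and 8 h arrays alone 1 gene, ESM1. Without course 1, 2 or 3 it called 247, 359 or 517 genes; HSPA1A, FGF21 and TGFA were not called without course 1 or without course 2, KRTAP2-3 and LRIG3 not without course 1, FAM111B not without course 1 or without course 2, MOK not without course 2, and ARHGAP9 and CDH3 not without any of the 3 courses.

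**Figure D3:**
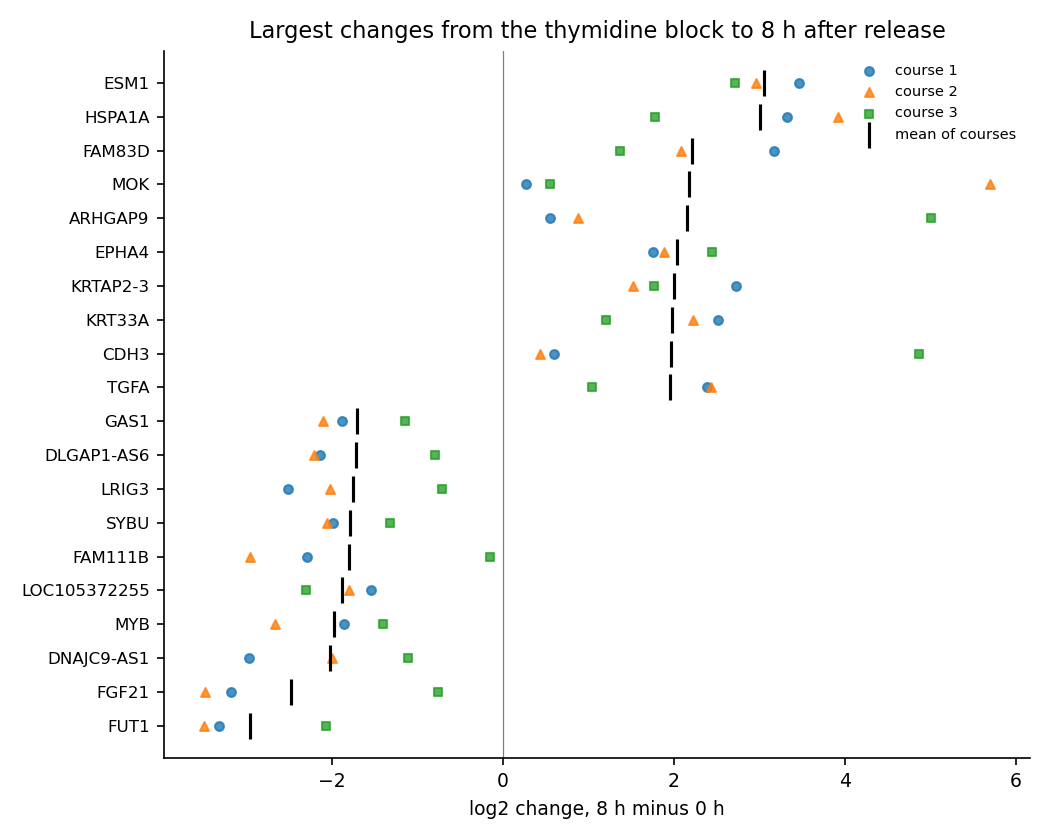
Change from 0 h to 8 h after double thymidine release, as log2, for named genes; the 3 kinds of point are the courses and the black marks their mean. ESM1 stands highest with a mean of 3.05 and FUT1 lowest with a mean of −2.96, and in MOK, ARHGAP9 and CDH3 a single course lies far from the other two.

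The thymidine-nocodazole course addressed the same cycle from a start in mitosis. No gene was called periodic in it by limma, at the period of 34 h found in its marker genes or at the 18.25 h of double thymidine. At 34 h, 867 genes had an unadjusted limma p under 0.05 where chance gives 917, and the smallest adjusted p was 0.0191. At 18.25 h, 713 genes had an unadjusted p under 0.05. The count of 867 depended on the processing. It ran from 510 without the first 6 h to 2365 with prewhitened values, and was 1443 with terms for interleaved sets of arrays. It thus does not show that waves are absent from this course. The FOXM1 and G2/M targets had a mean log ratio of 0.25 at 0 h and −0.96 at 12 h. The G1/S regulators had −0.73 at 0 h and 0.11 at 10 h, and the histones −0.55 at 0 h and 0.72 at 20 h. Adjusted over the list alone, 13 of 45 histone genes and 1 of 15 clock genes were called, and none of any other list. The number of genes called in both synchronisations was 0.

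Peak times were nonetheless related between the synchronisations. Fitted at 18.25 h, 164 of the 187 genes periodic after double thymidine (87.7%) peaked within 4.56 h of a common offset of −7.37 h in the thymidine-nocodazole course. MYB and CCNE1 had fitted peaks at 12.3 and 11.1 h there (unadjusted limma p 0.0061 and 0.0078), against 1.40 and 0.20 h after double thymidine. KIF20A and PLK1 had fitted peaks at 5.06 and 4.92 h, against 12.0 and 11.8 h, but their waves there were not detectable one by one (unadjusted limma p 0.67 and 0.21). The length of the mean offset vector was 0.665, against 0.0647 on average when peak times were permuted between genes (permutation p 1e-04, the smallest that 10000 permutations can give; genes are not independent replicates). The median fitted log2 peak-to-trough of these genes was 0.37 there and 0.68 after double thymidine, the data in which they were selected for their waves. A fitted peak-to-trough is always positive, so scatter alone can give part of the 0.37. In the thymidine-nocodazole course, 35 of the 187 had an unadjusted limma p under 0.05. The comparison at a common offset was chosen after the data were seen.

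The period of this course was not determined, since 34 h is the end of the range searched and a further maximum lay at 22.5 h, and double thymidine courses fitted alone called no more than 2, 12 and 12 genes. In this course 5189 genes differed between the 3 interleaved sets of arrays that each recur every 6 h. In data with added waves of 2-fold, of constant size and at the period of the fit, it recovered 22.4% of them, against 95.5% after double thymidine.

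**Figure D4:**
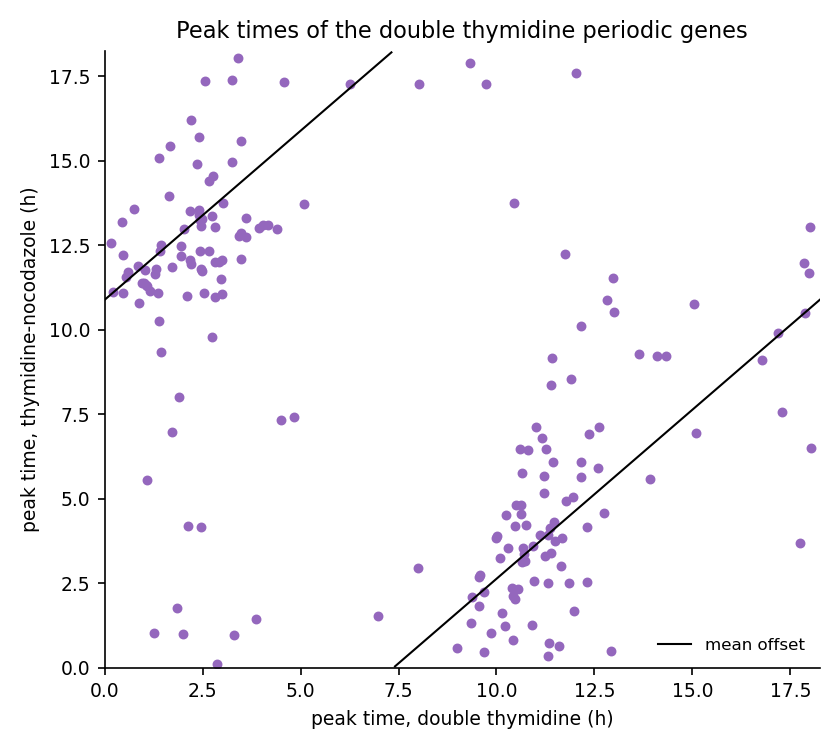
Fitted peak time in the thymidine-nocodazole course against that after double thymidine, in hours of an 18.25 h cycle, for the 187 genes periodic after double thymidine; each point is a gene and the line, which wraps around the cycle, marks the common offset of −7.37 h. Of the genes, 87.7% lie within 4.56 h of it.

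The last comparison tested whether the wave of a gene differs between the synchronisations, with the thymidine-nocodazole times moved to the phase of the marker genes. It called 1 gene of 18334, CTHRC1, which encodes a secreted protein of the extracellular matrix. The difference between its waves was 3.18-fold (limma adjusted p 0.00968). Its fitted fold was 3.01 in the thymidine-nocodazole course, without replicates, and 1.18 after double thymidine, where it was not periodic. In all, 1859 genes had an unadjusted p under 0.05. The test rests on a single thymidine-nocodazole course with a scatter pooled over all 4 courses, and in simulated data it called 8 unchanged genes. Fitted at 18.25 h, the median residual SD was 0.394 in the thymidine-nocodazole course and 0.241 to 0.332 after double thymidine. The p value can therefore be too small. CTHRC1 was not called with 18.25 h for both synchronisations, a period 2 h shorter or no trend. It was not called either without course 1, without course 3, without the 0 h arrays, without the second arrays of course 1 or with quantile normalization. The call thus depends on the undetermined 34 h period and on other choices made at that period.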

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

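The weighing tests of all 3 patterns, the slope comparison and the sets of arrays were chosen only after the result was seen; the counts under shuffled orders and other splits were planned.

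CTHRC1 had a wave that differed between the synchronisations, with a limma adjusted p of 0.00968. Its fold was 3.01 in the thymidine-nocodazole course and 1.18 after double thymidine. The test rests on 1 thymidine-nocodazole course with a scatter pooled over all 4 courses, and it called 8 unchanged genes in simulated data. Of 13795 probes with no gene named here, which no comparison used, 37 (0.268%) were periodic after double thymidine, against 1.02% of named genes. These shares are not a like comparison, since the first is over single probes and 7759 of the named genes are means over several probes. The largest wave was 2.26-fold, and 14 of the 37 probes peaked between 9.13 and 12.2 h.

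The first pattern is that no gene was called periodic in the thymidine-nocodazole course, while most double thymidine genes had fitted peaks there at a common offset. Fewer arrays stay open as an explanation, since double thymidine courses fitted alone called 2, 12 and 12 genes. Of the 96, 68 and 175 genes called in the other courses, though, 82.3%, 91.2% and 73.1% had an unadjusted limma p under 0.05 in the left-out course. In the thymidine-nocodazole course 26.7% (95% interval 20.5 to 33.7%) of the 187 genes did with terms for the interleaved sets of arrays, and 18.7% (13.4 to 25.1%) without. The gene sets differ, and all fits used 18.25 h, a period set on the double thymidine courses. These shares are thus not a like comparison. The choice of period stays open too: the number of calls was 0 at every whole-hour period from 14 to 34 h and 2 at 36 h, as many as in course 1 alone. A larger scatter and a weaker wave cannot be told apart: with terms for the interleaved sets of arrays the residual SD was 0.336, against 0.242 to 0.327 after double thymidine, a smaller gap than without them (0.394 against 0.241 to 0.332), and the median wave was 0.393 of that after double thymidine (95% interval 0.345 to 0.456), below left-out courses 1 and 2 of double thymidine at 0.954 (0.908 to 1.03) and 1.07 (1.03 to 1.11) but not clearly below course 3 at 0.452 (0.422 to 0.513). The 95% intervals given here are over genes, which are not independent replicates, and hold no spread between courses. The thymidine-nocodazole ratio was taken at an offset fitted to the same 187 genes, those of the left-out courses without an offset. A difference between release from mitosis and release from the G1/S border stays open and untested, since the thymidine-nocodazole synchronisation was run 1 time.

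The second pattern is the rise of heat shock genes at 8 to 12 h after double thymidine release. Their second-cycle ratio was 0.0605 ± 0.0898 (SD, n = 3 courses) against 0.359 ± 0.0547 for the FOXM1 and G2/M targets, which is consistent with a single response to release in place of a wave of the cell cycle. Swings of whole arrays that housekeeping and ribosomal genes follow do not account for the rise: from 0 h to the mean of 8 to 12 h the mean of those genes changed by −0.05 ± 0.15 (log2, SD, n = 3 courses), which at the fitted coefficient gives 0.16 ± 0.48 of the rise of 1.80 ± 0.12 in the 4 periodic heat shock genes. With that mean as a covariate, HSPA8 stayed called as periodic; the call of HSPA1A ended on its adjusted p, which went from 0.00911 to 0.0304 as the fold went from 2.73 (log2 SE 0.34) to 2.10 (0.29), while HSPH1 and BAG3 fell under the minimum fold, from 1.60 (0.14) to 1.45 (0.12) and from 1.54 (0.13) to 1.45 (0.13), with BAG3 also at an adjusted p of 0.0106. The handling of cells at release was not tested and stays open.

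A last pattern is a repeat of 3 arrays in course 1 and in the thymidine-nocodazole course. Between the 3 interleaved sets of arrays that each recur every 6 h, 5189 genes differed at an adjusted p under 0.05 in the thymidine-nocodazole course and 1141 in course 1, where the arrays marked as second form one such set; sets that recur every 8 h gave 7 and 0 genes. A rhythm of the cells of 6 h would be expected in all courses, and courses 2 and 3 gave 0 genes. Arrays processed in 3 technical sets are a candidate explanation; the labels of the thymidine-nocodazole course name no such sets.

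With the time order of the arrays shuffled within courses, 100 orders were compared, the real one included. The real order gave 187 periodic genes after double thymidine and 9 enriched lists, and the highest of the others was 0 for both. A random order of arrays thus did not give these counts. Shuffling kept the fitted period and broke any smooth change over time, so it cannot tell a recurring wave from a single change. For the thymidine-nocodazole course the real value and the highest other were both 0; all 100 orders gave as many, which a count of 0 fixes, so this says nothing about chance there. The 10 splits of the 0 h and 8 h arrays are too few for a share under 0.05: the real split gave 820 genes and the highest other 1. For the lists at the preset correlation the real split gave 12 and the others 2 to 12, so 2 splits in all gave 12, of too few again. Among the others, the splits that took 1 array from each course gave 9, 2 and 8 lists. With an estimated correlation the real split gave 8 and the highest other 0. With each of the 4 courses taken in turn as the odd one, also too few, the wave difference gave 1 gene for the real one and 0 as the highest other.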

How the results depend on the processing

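The alternatives marked as added were chosen only after the result was seen. The number of enriched lists stayed within 7 to 11 and that of shifted lists within 8 to 15 under the alternatives run, the double thymidine period within 17 to 19 h, and the second-cycle ratio within 0.269 to 0.319. Of the named genes' waves, 2210 values stayed on their side of the limits, 95 lost and 5 gained a call and 0 reversed; of the named genes' changes at 8 h, 277 stayed, 43 lost the call and 0 reversed; of list shifts, 153 stayed, 9 lost and 5 gained a call, and that of replication-dependent histones, uncalled with all courses, was called higher without course 1 and reversed, called lower, without course 3 (direction 1 and −1). Filters on missing values changed nothing, as no value is missing.

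For the 187 double thymidine genes, no minimum fold gave 581, 2-fold 22, a period 2 h shorter 120 and leaving out a course 68 to 175; the latter has fewer arrays. The step from G1/S to G2/M peaks was 8.95 h with the shorter period, by its construction. For the 0 thymidine-nocodazole genes, quantile normalization gave 4, a period 2 h longer 2 and prewhitening 12. The 34 h period became 18.25 h with the G1/S list alone, 24.5 h with the FOXM1 and G2/M list alone, 23.25 h with no trend and 21.75 h without 0 h arrays, all added. For the 1 gene of the wave difference, quantile normalization, no trend, a period 2 h shorter, no 0 h arrays and no second arrays gave 0, the most variable probe 4, a period 2 h longer 2, prewhitening 6, leaving out a course 0 to 1, and, added, the double thymidine period 3 and terms for the array sets 11; CTHRC1 was not among the 3 but was in each of the other sets with a call. For the 820 genes at 8 h, 2-fold gave 280, no second arrays 526, no course block 336, only the 0 h and 8 h arrays 1, and leaving out a course 247 to 517. With a period 2 h longer, the mean peak time of condensin and cohesin reversed to 6.25 h and the mean peak time of cyclins, CDKs and their inhibitors to 19.3 h. The latter ran from 0.574 h, reversed, without course 2 to 12.8 h without course 1, and the mean peak time of replication-dependent histones from 3.79 h without course 2 to 16.9 h, reversed, without course 3. Apart from the limits on fold and the smaller numbers of arrays, the cause was not tested. Signal over background was not in the table, so what it limits is unknown.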

Other observations

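The slope tests were chosen only after the result was seen. Their limma p values rest on the scatter of single arrays and not on the spread of slopes between courses. That scatter was pooled over all 4 courses. With terms for the array sets, the median residual SD was 0.336 in the thymidine-nocodazole course and 0.242 to 0.327 after double thymidine. The p values and SEs given for the thymidine-nocodazole course can therefore be too small. Beside waves of 18.25 h, the period used for both synchronisations in this fit, levels drifted over the hours after release. The period of the thymidine-nocodazole course was not determined. A slow wave in that course therefore cannot be told apart from a drift, nor can a slope difference that rests on it. In the thymidine-nocodazole course, p53 targets drifted upward: 8 of 20 rose by at least 1.5-fold over 38 h at an adjusted p under 0.01 in limma, and none fell, with a median log2 change of 0.65 and a camera adjusted p of 8.1e-11, or 0.028 with an estimated correlation. The genes were SESN1 at 1.41 ± 0.19 (SE of the fit), RRM2B at 1.29 ± 0.20, FAS at 1.18 ± 0.16, DDB2 at 1.16 ± 0.15, MDM2 at 0.90 ± 0.13, PHLDA3 at 0.86 ± 0.21, PPM1D at 0.85 ± 0.14 and CDKN1A at 0.75 ± 0.18, chosen after their values were seen. After double thymidine, none of the 20 rose and 2 fell. The slope differed between the synchronisations for 14 of the 20 genes, all higher in the thymidine-nocodazole course (median 0.85; adjusted p 2.1e-09, and 0.068 with an estimated correlation, so not called as a list). This course has no replicate. The fit held terms for the 3 interleaved sets of arrays, and the slope of the list's mean log ratio over 38 h within each set, not tested for a difference, was 1.03 ± 0.19 (SE of the fit) in the 8 arrays from 0 to 42 h, 0.29 ± 0.21 in the 8 from 2 to 44 h and 0.67 ± 0.22 in the 7 from 4 to 40 h.

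After double thymidine, other groups drifted. Of 45 histone genes, 27 rose over 38 h and none fell, with a median of 0.73 and an adjusted p of 0.030 with an estimated correlation. Of 14 hypoxia and glycolysis genes, 5 rose and none fell, with a median of 0.42 (2.4e-05 with an estimated correlation). Of 16 ATF4 and unfolded protein genes, 7 fell and 1 rose, with a median of −0.56 (0.030 with an estimated correlation). Of 14 cholesterol synthesis genes, 2 rose, with a median of 0.28 (0.030 with an estimated correlation). Of 18 immediate early genes, 7 fell, which is not called with an estimated correlation (adjusted p 0.12).

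Over all genes, 407 rose and 569 fell over 38 h after double thymidine, 653 rose and 351 fell in the thymidine-nocodazole course, and 1752 differed in slope between the synchronisations. Taking each of the 4 courses as the odd one gave at most 37 genes for another course; 4 courses are too few for a share under 0.05.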
